A study of Homo sapiens with 24 samples.

How the data were processed

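RNA of 24 samples of the SAS cell line was sequenced by the authors in 8 groups of 3: 2 genotypes of NRF2 (WT and E79Q), each under 4 treatments (untreated, CB-839 at 0.1 µM, radiation at 4 Gy, or both). The series text describes 12 samples in 4 irradiated groups, whereas the sample labels and the deposited table hold 24 libraries in 8 groups, and all 24 were used. Whether the 12 others were made with them is not stated, so a batch is not excluded in the radiation comparisons. The last 3 columns of the table carry a shortened name and were taken as irradiated E79Q cells with CB-839 from the sample titles. The labels do not say whether replicates were separate cultures.

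The deposited table holds raw read counts per Ensembl gene, with no normalization, and the deposited gene_length column holds other values, lengths in base pairs. The notes of the authors name STAR, HTSeq and the GRCh38 build, with no order or role. Their versions, the annotation release, the strand setting and any trimming are not given in the sources used here. All 58735 gene IDs and coordinates of the table were found in GENCODE release 29, and 58708 gene names matched it. Older gene symbols were kept as the table gives them, such as CTGF for CCN2. Total counts ran from 14285084 to 23640197 per library.

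Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr over the 8 groups, which left 15956 of 34983 genes with any read. Libraries were scaled by TMM, and CPM values use the scaled library sizes. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries with 16 residual degrees of freedom, and the common biological coefficient of variation was 7.19%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 15956 genes, separately in each comparison. With 3 libraries against 3, an exact test on a single gene cannot give a p under 0.1, so the calls rest on the spread pooled across genes by edgeR. Standard errors are of log2 fold changes from that model, and log CPM for plots and correlations used a prior count of 2.

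There were 17 comparisons: E79Q against WT in each treatment, radiation against none in each genotype with and without CB-839, CB-839 against vehicle in each genotype with and without radiation, the differences between genotypes in those radiation and drug effects, and the drug effect averaged over the 4 pairs. A difference is the effect in E79Q cells minus that in WT cells. Overlaps of calls were compared with the number expected if the calls were independent.

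Before the data were examined, 23 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists were tested with camera, 2-sided, at a preset correlation between genes of 0.01 and again with a correlation estimated for each list, and with fry, and p was adjusted over the 23 lists in each comparison. Counts within a list were also adjusted over the list alone. Camera at the preset correlation and with the estimated one gave the same call in 319 of the tests and lost it in 72. Named genes were those with a symbol, protein coding where annotated, with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the replicates of the groups compared. Of these, the 6 largest rises and 6 largest falls could be named in the genotype comparisons without CB-839 and in the radiation comparisons without CB-839, and the 3 largest each way in the others, where overlap was not asked of differences and the average. In addition the 2 members of each list with the smallest p in each direction could be named, or the 2 of highest expression where none passed, and in any comparison NFE2L2, KEAP1, NQO1, GCLM, TXNRD1, SLC7A11, CDKN1A, MDM2, CXCL1, CXCL8, CSF1, CSF2, IL6 and CD274. Some genes that this rule allowed are not reported here. Where the text follows a gene of one comparison into a figure caption, its values are shown without a further test.

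The alternatives were DESeq2, limma-voom, other scaling factors, no filter, a filter of 1 CPM in 12 libraries, a fit of the compared groups alone, a test against a 1.5-fold change, the replicate number as a block, and leaving out each library in turn. Removal of trends on GC content and gene length through offsets (lowess span 0.3) and a fit without 4 libraries were chosen after seeing the data. GC content was available for 99.97% of the tested genes. The procedure was tested on simulated data made from these counts: for untreated E79Q against WT it recovered 56%, 70% and 90% of the changed genes at 1.5, 2 and 4-fold. For the difference in radiation effect it recovered 40%, 56% and 84%, and for the average drug effect 86%, 94% and 100%.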

Results

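RNA was measured in SAS cells, a line from a human oral squamous carcinoma, that carried wild-type (WT) NRF2 or its E79Q form. NRF2, encoded by NFE2L2, is the transcription factor that switches on antioxidant and detoxifying genes, and KEAP1 is the protein that holds it in check. The cells had received CB-839, a drug that limits the use of glutamine, at 0.1 µM or vehicle, and radiation at 4 Gy or none. Drug or vehicle was given 24 h ahead of radiation and RNA was taken 24 h after it. Whether the drug stayed on after radiation, and when RNA of unirradiated cells was taken, is not stated. The 24 libraries fell into 8 groups of 3: each of the 2 genotypes untreated, with CB-839, irradiated, and irradiated with CB-839. In all, 15956 genes were tested. Levels are given as CPM, counts scaled for library size. The counts do not show the allele itself.

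On GRCh38, NFE2L2 (ENSG00000116044) lay on chromosome 2 at 177227595 to 177392697, KEAP1 (ENSG00000079999) on chromosome 19 at 10486120 to 10503741 and NQO1 (ENSG00000181019) on chromosome 16 at 69706996 to 69726951. SLC7A11 (ENSG00000151012) lay on chromosome 4 at 138164097 to 138242349 and CDKN1A (ENSG00000124762) on chromosome 6 at 36676460 to 36687339. CXCL8 (ENSG00000169429) lay on chromosome 4 at 73740506 to 73743716 and CXCL1 (ENSG00000163739) on the same chromosome at 73869393 to 73871242. Each is annotated as protein coding, and every value below covers the whole gene.

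Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.985 to 0.992 between libraries of a group and 0.969 to 0.989 between libraries of different groups. The share of counts from mitochondrially encoded genes was 1.93% to 3.55%. In 4 libraries the deviation from the group mean followed the GC content of the genes. These were library 2 of irradiated E79Q cells with CB-839 (r 0.77), library 1 of irradiated WT cells with CB-839 (r 0.63), library 1 of untreated E79Q cells (r 0.51) and library 3 of WT cells with CB-839 (r 0.49), each across genes. Deviations from a mean of 3 libraries sum to 0, so opposite deviations in the other libraries of a group are no sign of a trend of their own. Replicate numbers did not pair the libraries, since 6 of the 24 correlated best with libraries of their own number. Reads of close paralogs, such as AKR1C1 and AKR1C2 or CXCL1 and CXCL3, can be shared or lost in counting, so their separate values carry that limit. The labels do not say that the replicates were separate cultures, so every p-value measures only the spread between these samples. If the unirradiated libraries were made apart from the others, each radiation effect below also holds the difference between the 2 runs.

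**Figure D1:**
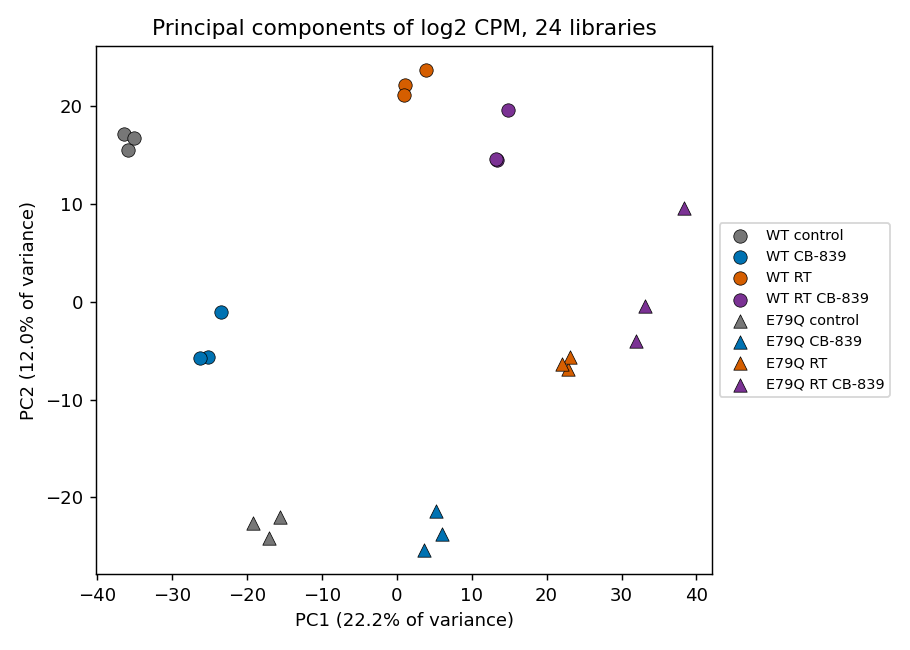
Principal components of log2 CPM over all tested genes, with 1 point per library, colour for treatment and marker for genotype; the axes give component scores. Component 1 held 22.2% of the variance and component 2 held 12.0%, and on component 1 the libraries ran from -36.4 (untreated WT cells) to 38.4 (irradiated E79Q cells with CB-839).

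Untreated E79Q cells had more RNA from NRF2 target genes and less from squamous genes than untreated WT cells. Hypoxia and stress response genes were lower too, but did not pass as lists after radiation. AKR1C1, an aldo-keto reductase, was at 58.1 ± 3.22 CPM against 7.83 ± 1.16 (mean ± SD, n = 3 in each group), a log2 fold change of 2.89 (SE 0.10, adjusted p = 1.01e-17). Values in parentheses after a gene are log2 fold changes, with their standard error (SE) where given. IGFBP3, which binds insulin-like growth factors, was at 8.65 ± 1.07 CPM against 105 ± 3.29 (-3.60, SE 0.100, adjusted p = 7.93e-20). MMP1, a collagenase, rose from 198 ± 11.2 to 761 ± 58.2 CPM (1.94, SE 0.055, adjusted p = 7.93e-20), and KRT17, a keratin, fell from 450.4 ± 6.50 to 173 ± 7.64 CPM (-1.38, SE 0.076, adjusted p = 1.78e-13). In all, 3149 genes differed, 1535 higher and 1614 lower in E79Q cells, 498 of them by over 2-fold. Among the largest rises were also AKR1C2 (2.76 on the log2 scale, SE 0.16), SPP1 (2.71, SE 0.23), TLR4 (2.47, SE 0.17) and HKDC1 (2.35, SE 0.28). Among the largest falls were NGFR (-2.34, SE 0.19), NOTCH3 (-2.23, SE 0.16), DDIT4, an inhibitor of mTORC1 signalling (-2.23, SE 0.091), and the kallikrein KLK10 (-2.17, SE 0.085).

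Below, the median of a list is that of its members' log2 fold changes, and camera's p is adjusted over the 23 lists. Of the 3 lists of NRF2 targets, the glutathione and thioredoxin list shares CHAC1 with the ATF4 list below. It had 9 of 12 genes higher and 1 lower in untreated E79Q cells, the same adjusted over the list alone (median 0.41, camera adjusted p = 8.7e-11). The detoxification, iron and transport list had 19 of 29 higher, 21 adjusted over the list alone, and 0 lower (median 0.44, camera adjusted p = 1.22e-24). The NADPH and pentose phosphate list had 4 of 8 higher and 1 lower and did not pass as a list (median 0.16, camera adjusted p = 0.843). Its member IDH1, which makes NADPH in the cytosol, fell (-0.92, SE 0.054, adjusted p = 6.85e-13). NQO1, a quinone reductase, rose from 354 ± 3.06 to 587 ± 22.1 CPM (0.73, SE 0.066, adjusted p = 2.36e-09). The thioredoxin reductase TXNRD1 rose by 0.73 on the log2 scale, the cystine transporter SLC7A11 by 0.57 and the glutathione peroxidase GPX2 by 1.99. GCLM, a subunit of the enzyme that starts glutathione synthesis, did not pass (log2 fold change 0.06, adjusted p = 0.434). NFE2L2 itself fell by 0.33 on the log2 scale and KEAP1 rose by 0.57.

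**Figure D2:**
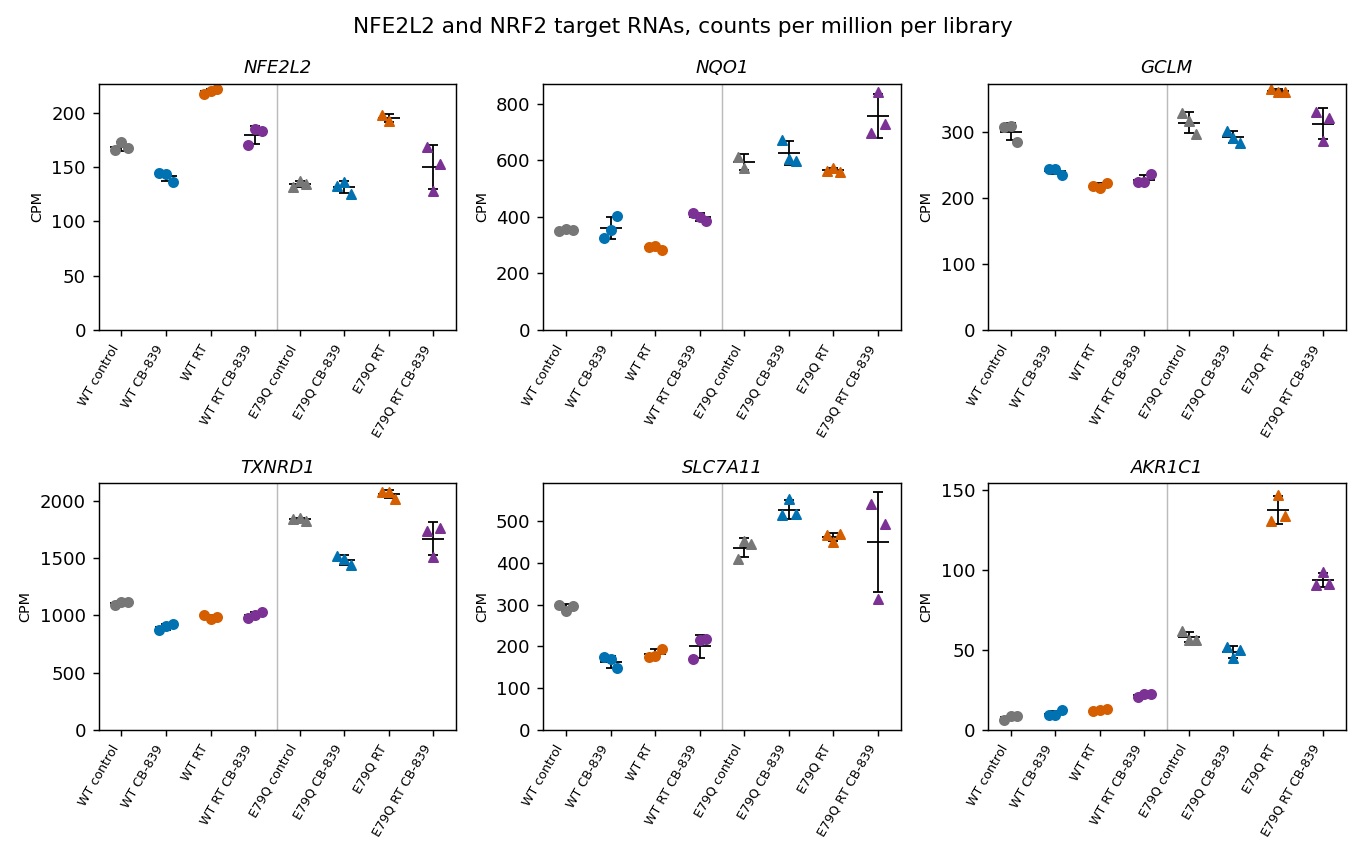
CPM of NFE2L2, NQO1, GCLM, TXNRD1, SLC7A11 and AKR1C1 in each of the 24 libraries (points), with the mean and SD of each group of 3. AKR1C1 was at 7.83 ± 1.16 CPM in untreated WT cells and 138 ± 8.67 CPM in irradiated E79Q cells.

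Squamous differentiation genes were lower in untreated E79Q cells in 12 of 18 cases and higher in 0, with the same counts adjusted over the list alone (median -0.78, camera adjusted p = 6.89e-17). KLK5, a protease of the cornified layer, changed by -1.06 on the log2 scale. Mesenchymal genes rose, with 11 of 24 higher and 3 lower, and 12 and 3 adjusted over the list alone (median 0.24, camera adjusted p = 7.62e-14). Among them, CTGF, a matricellular protein, rose by 2.08 and the intermediate filament gene VIM by 1.99 on the log2 scale. Targets of ATF4, the transcription factor of the amino acid response, fell in 15 of 23 cases and rose in 1, and in 16 and 1 adjusted over the list alone (median -0.38, camera adjusted p = 1.62e-10). Hypoxia and glycolysis genes had 10 of 23 lower and 0 higher, 11 and 1 adjusted over the list alone (median -0.17, camera adjusted p = 1.43e-05). NDRG1, a hypoxia-induced gene of that list, changed by -1.48 on the log2 scale. Unfolded protein response genes had 7 of 18 lower and 0 higher, 12 lower adjusted over the list alone (median -0.22, camera adjusted p = 1.31e-05), including the chaperone gene HSPA5 (-0.49). Cholesterol synthesis genes had 9 of 21 lower and 1 higher, unchanged adjusted over the list alone (median -0.18, camera adjusted p = 0.000911).

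Mitotic genes were higher in untreated E79Q cells, 13 of 30 with 0 lower and 14 adjusted over the list alone (median 0.15, camera adjusted p = 3.61e-05), as for the kinase gene PLK1 (0.35). Antigen presentation genes had 8 of 20 lower and 0 higher, 11 and 1 adjusted over the list alone (median -0.21, camera adjusted p = 0.00492), among them the immunoproteasome gene PSMB9 (-0.64). Interferon response genes had 6 of 26 lower and 0 higher, 9 lower adjusted over the list alone (median -0.35, camera adjusted p = 0.00377). Targets of p53 had 10 of 31 lower and 3 higher, 10 and 5 adjusted over the list alone (median -0.012, camera adjusted p = 0.0188), and without library 2 of untreated WT cells the list no longer passed (adjusted p = 0.052). Of them, GDF15, a secreted stress cytokine, changed by -2.03 and CDKN1A, which encodes the cell cycle inhibitor p21, by -0.55. The list of secreted proteases and senescence-associated factors had 11 of 23 higher and 6 lower, the same adjusted over the list alone (median 0.31, camera adjusted p = 0.00643; adjusted p = 0.245 with an estimated correlation). The mitochondrially encoded list had 6 of 13 lower, 10 adjusted over the list alone, and 0 higher (median -0.25, camera adjusted p = 0.00117; adjusted p = 0.361 with an estimated correlation, and adjusted p = 0.0551 without library 1 of untreated E79Q cells, whose mitochondrial share was 1.93%).

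Targets of NF-kB had 1 of 19 higher and 5 lower in untreated E79Q cells. Their median (0.012) and mean (-0.24) differed in sign, and camera placed them lower (adjusted p = 0.042; adjusted p = 0.131 with an estimated correlation). Without library 1 of untreated WT cells, or library 2 or 3 of untreated E79Q cells, that list did not pass (adjusted p = 0.0586, 0.0729 and 0.107). Myeloid chemokines and cytokines had 4 of 21 higher and 6 lower and did not pass as a list (adjusted p = 0.724). The neutrophil attractant CXCL8 rose from 8.81 ± 0.730 to 15.9 ± 0.180 CPM (0.85, SE 0.090, adjusted p = 5.58e-08), and S100A9 fell (-1.47, SE 0.15, adjusted p = 4.77e-08). The glutamine metabolism and transport list had 5 of 22 higher and 7 lower (median -0.050, camera adjusted p = 0.843). Its member GPT2, an alanine transaminase that uses glutamate, changed by -0.59. The other lists did not pass. Camera gave adjusted p = 0.184 for DNA replication and G1/S genes (5 of 30 higher, 2 lower), 0.724 for replication-dependent histones (0 of 13 either way) and 0.987 for homologous recombination and end joining (1 of 29 lower). It gave 0.308 for immediate early genes (4 of 17 higher, 3 lower) and 0.724 for markers of leukocytes, endothelium and fibroblasts (2 of 8 higher, 2 lower). Camera's direction was opposite to the sign of the median for chemokines, glutamine, homologous recombination and immediate early genes, and median and mean had opposite signs for immediate early genes and the markers. COL1A1 and COL1A2, collagen genes that were both called higher, rested on library 2 of untreated E79Q cells (29.6 and 15.3 CPM there) and were not called without it (adjusted p = 0.562 and 0.73).

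The series concerns NFE2L2 mutations, radiation and myeloid cells, so the genotypes were also compared after radiation. Irradiated E79Q cells had more RNA from 2 of the 3 lists of NRF2 targets and from myeloid chemokines than irradiated WT cells. AKR1C1 was at 138 ± 8.67 CPM against 12.4 ± 0.803 (3.47, SE 0.095, adjusted p = 7.68e-20; n = 3 in each group). SLC7A11 was at 462 against 182 CPM (1.34, SE 0.12, adjusted p = 3.42e-09). CXCL8 was at 60.6 ± 5.55 CPM against 19.3 ± 1.08 (1.65, SE 0.076, adjusted p = 4.52e-15). CXCL1, another neutrophil attractant, was at 122 ± 6.35 against 71.6 ± 4.90 (0.77, SE 0.092, adjusted p = 6.35e-07). CD274, which encodes the checkpoint ligand PD-L1, was at 24.5 ± 0.673 against 16.9 ± 1.45 (0.54, SE 0.11, adjusted p = 0.00113). Of the 1538 genes that differed, 748 were higher and 790 lower, and 259 differed by over 2-fold. The count was 3025 with the groups compared alone and 2400 with trends removed. The largest rises also took in HKDC1 (3.30, SE 0.22), AKR1C2 (3.24, SE 0.15), the protease-activated receptor gene F2RL2 (2.88, SE 0.13) and OSGIN1 (2.09, SE 0.096), and the largest falls IGFBP3 (-2.39, SE 0.099), MTUS1 (-1.87, SE 0.16) and SYT12 (-1.62, SE 0.078).

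In irradiated E79Q cells 11 of 12 glutathione and thioredoxin genes were higher, 12 adjusted over the list alone (median 0.70, camera adjusted p = 9.71e-50), among them GCLM (0.73) and TXNRD1 (1.06). Of the detoxification, iron and transport genes 26 of 29 were higher, as many adjusted over the list alone (median 0.78, camera adjusted p = 3.68e-100), NQO1 with them (0.95). The NADPH and pentose phosphate list had 4 of 8 higher and 1 lower and did not pass (median 0.22, camera adjusted p = 0.2), and its member IDH1 fell (-0.87, SE 0.056, adjusted p = 4.61e-12). Myeloid chemokines and cytokines had 9 of 21 higher and 2 lower, 10 and 3 adjusted over the list alone (median 0.37, camera adjusted p = 1.13e-05). The proteases and senescence-associated factors had 12 of 23 higher and 3 lower, 14 and 5 adjusted over the list alone (median 0.35, camera adjusted p = 4.98e-06; adjusted p = 0.0739 with an estimated correlation), MMP1 with them (1.16). Mesenchymal genes had 11 of 24 higher and 2 lower, 13 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 1.9e-15). Squamous differentiation genes had 9 of 18 lower, as many adjusted over the list alone (median -0.46, camera adjusted p = 1.13e-11). Cholesterol synthesis genes had 15 of 21 lower, 16 adjusted over the list alone (median -0.27, camera adjusted p = 2.39e-13), such as STARD4 (-1.16). The ATF4 (median -0.018, camera adjusted p = 0.746), hypoxia (-0.045, 0.739), unfolded protein response (-0.077, 0.299) and NF-kB lists (0.20, 0.2) did not pass. The irradiated and untreated genotype differences shared 495 higher and 607 lower genes, where 71.96 and 79.91 were expected if the calls were independent, and 9 genes went opposite ways, where 152 were expected.

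**Figure D3:**
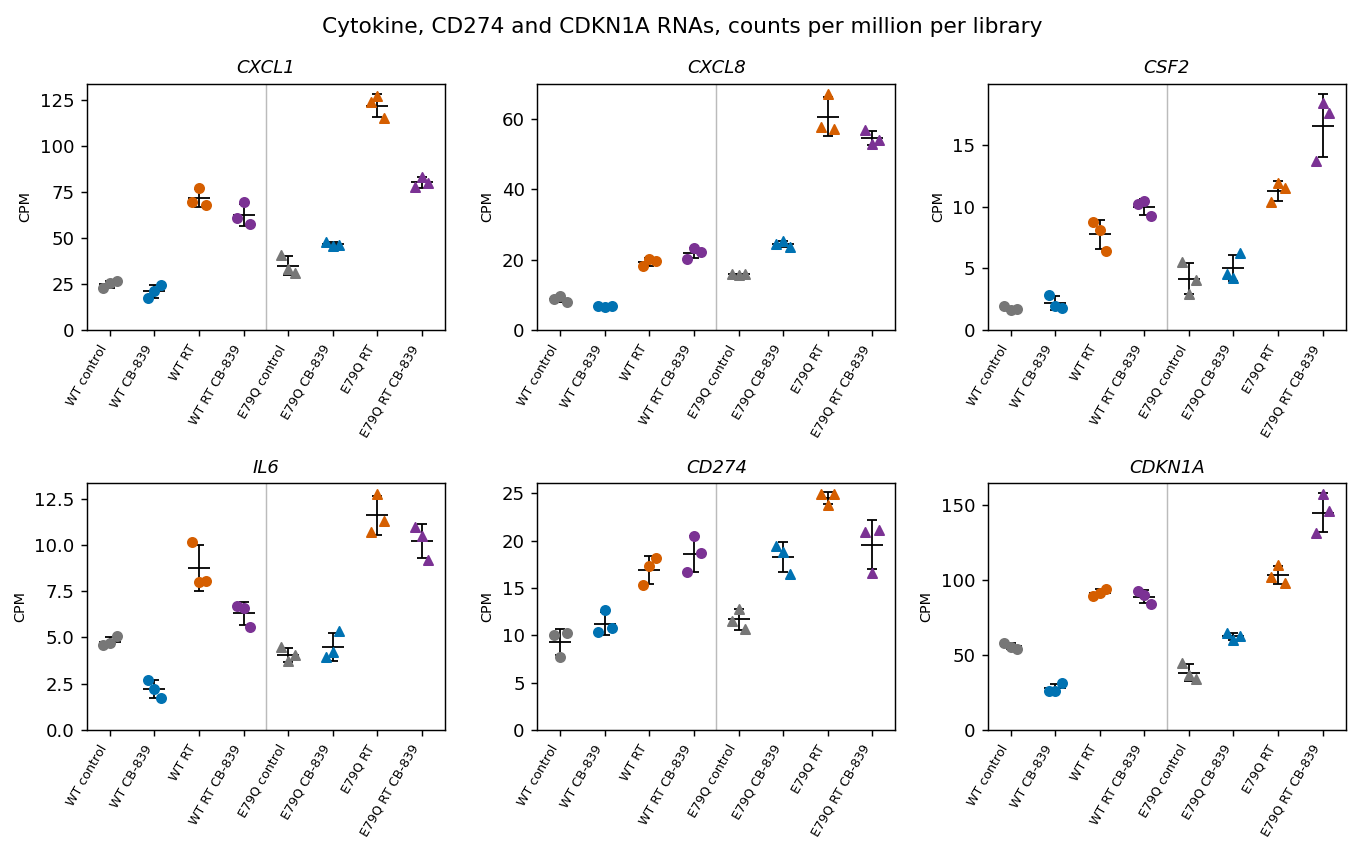
CPM of CXCL1, CXCL8, CSF2, IL6, CD274 and CDKN1A in each of the 24 libraries (points), with the mean and SD of each group of 3. CXCL8 was at 8.81 ± 0.730 CPM in untreated WT and 60.6 ± 5.55 in irradiated E79Q cells.

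Among cells given CB-839 without radiation, the genotypes differed in NRF2 targets and also in ATF4 targets, chemokines and the unfolded protein response. SLC7A11 was at 528 ± 21.6 CPM in E79Q and 163 ± 14.2 in WT cells (1.69, SE 0.12, adjusted p = 2.97e-11; n = 3 in each group). AKR1C1 was at 48.9 ± 3.68 and 10.2 ± 1.73 (2.25, SE 0.099, adjusted p = 1.97e-15). STC2, a secreted ATF4 target, was at 245 ± 6.48 and 105 ± 4.84 (1.23, SE 0.046, adjusted p = 9.07e-17). CDKN1A was at 62.6 ± 2.33 and 27.7 ± 3.0 (1.17, SE 0.088, adjusted p = 7.7e-11). CXCL8 was at 24.4 ± 0.919 and 6.81 ± 0.304 (1.84, SE 0.091, adjusted p = 2.14e-14). There were 2396 genes, 1324 higher and 1072 lower in E79Q cells, with ANGPTL4 (2.57, SE 0.30) and SPP1 (2.29, SE 0.22) among the largest rises and ELF3 (-2.09, SE 0.11) and NGFR (-2.03, SE 0.22) among the largest falls. The ATF4 list had 19 of 23 higher, as many adjusted over the list alone (median 0.85, camera adjusted p = 8.88e-50). The unfolded protein response had 13 of 18 higher, 14 adjusted over the list alone (median 0.27, camera adjusted p = 7.33e-12). The glutathione and thioredoxin list had 10 of 12 higher (median 0.74, camera adjusted p = 7.18e-23). The detoxification list had 22 of 29 higher (median 0.77, camera adjusted p = 1.45e-43), and the NADPH list did not pass (median 0.21, camera adjusted p = 0.675). Chemokines and cytokines had 12 of 21 higher and 2 lower (median 0.63, camera adjusted p = 5.37e-14). NF-kB targets had 15 of 19 higher and 2 lower (median 0.52, camera adjusted p = 6.95e-11), among them TNFAIP3, a feedback inhibitor of NF-kB (1.16). Squamous genes (median -0.62, camera adjusted p = 5.69e-13) and cholesterol synthesis genes (median -0.30, camera adjusted p = 4.36e-13) were lower, and mesenchymal genes (median 0.21, camera adjusted p = 6.14e-13) and the protease list (median 0.65, camera adjusted p = 3.65e-16) were higher. Adjusted over the list alone, 10 glutathione, 23 detoxification, 13 chemokine and 15 NF-kB genes were higher.

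With both radiation and CB-839, E79Q cells again held more RNA of NRF2 targets, chemokines and ATF4 targets than WT cells. AKR1C1 was at 93.6 ± 4.41 CPM in E79Q and 21.9 ± 0.912 in WT cells (2.10, SE 0.088, adjusted p = 2.33e-15; n = 3 in each group). CXCL8 was at 54.6 ± 1.94 and 21.9 ± 1.5 (1.32, SE 0.075, adjusted p = 1.19e-12), and the collagen gene COL12A1 at 11.9 ± 2.40 and 37.4 ± 3.47 (-1.65, SE 0.12, adjusted p = 1.3e-10). Each of the 12 glutathione and thioredoxin genes was higher, over all genes and adjusted over the list alone (median 0.71, camera adjusted p = 4.48e-41), and 23 of 29 detoxification genes, as many adjusted over the list alone (median 0.83, camera adjusted p = 8.67e-95). The NADPH list passed at the preset correlation (median 0.22, camera adjusted p = 0.0102; adjusted p = 0.0851 with an estimated correlation). Chemokines and cytokines had 11 of 21 higher and 1 lower, the same adjusted over the list alone (median 0.29, camera adjusted p = 3.31e-10). ATF4 targets had 15 of 23 higher, 17 adjusted over the list alone (median 0.44, camera adjusted p = 4.55e-24), with PSAT1, a serine synthesis enzyme, at 0.48. Camera also placed NF-kB targets (median 0.30, camera adjusted p = 5.96e-08), the protease list (median 0.30, camera adjusted p = 4.02e-11), the unfolded protein response (median 0.14, camera adjusted p = 0.000225) and mesenchymal genes (median 0.11, camera adjusted p = 6.52e-08) higher. It placed squamous (median -0.30, camera adjusted p = 1.34e-06) and cholesterol synthesis genes (median -0.25, camera adjusted p = 1.05e-15) lower. In all 1159 genes differed, 702 higher and 457 lower, and the count was 755 without library 3 of irradiated WT cells with CB-839. Library 2 of the E79Q group deviated along GC content (r 0.77). With trends removed 2093 genes were called, and 225 with the groups compared alone.

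Radiation of WT cells raised RNA of chemokines, NF-kB targets, secreted proteases and mesenchymal genes. CXCL1 went from 24.9 ± 1.82 to 71.6 ± 4.90 CPM (1.52, SE 0.100, adjusted p = 7.65e-12; n = 3 in each group). CSF2, a growth factor for myeloid cells, went from 1.74 ± 0.164 to 7.75 ± 1.20 (2.15, SE 0.21, adjusted p = 2.06e-08). CXCL8 went from 8.81 ± 0.730 to 19.3 ± 1.08 (1.13, SE 0.088, adjusted p = 2.05e-10). CDKN1A went from 55.9 ± 1.98 to 91.6 ± 2.34 (0.71, SE 0.082, adjusted p = 2.63e-07). CD274 went from 9.32 ± 1.37 to 16.9 ± 1.45 (0.86, SE 0.12, adjusted p = 6.97e-06). DDIT4 dropped from 107 ± 3.41 to 27.2 ± 2.09 (-1.98, SE 0.090, adjusted p = 4.66e-15). Of 2855 genes, 1501 rose and 1354 fell, 416 by over 2-fold. The count was 4354 with the groups compared alone. The largest rises held ZBED2 (2.54, SE 0.12), MAOA (2.26, SE 0.16), CSF3, which drives neutrophil production (2.20, SE 0.22), and HSD11B1 (2.12, SE 0.095), and the largest falls NANOS1 (-1.54, SE 0.079), DIO2 (-1.53, SE 0.11) and SYT12 (-1.38, SE 0.071).

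In irradiated WT cells 13 of 21 chemokines and cytokines rose and 1 fell, 14 and 2 adjusted over the list alone (median 0.57, camera adjusted p = 2.08e-12). NF-kB targets rose in 11 of 19 cases and fell in 1, in 11 and 2 adjusted over the list alone (median 0.40, camera adjusted p = 2.13e-09), as for TNFAIP3 (1.34). Proteases and senescence-associated factors had 15 of 23 higher and 3 lower, 16 and 3 adjusted over the list alone (median 0.67, camera adjusted p = 1.16e-23). Mesenchymal genes had 12 of 24 higher and 1 lower, 15 and 2 adjusted over the list alone (median 0.48, camera adjusted p = 2.04e-16), the fibronectin gene FN1 with them (1.20). Immediate early genes had 8 of 17 higher (median 0.27, camera adjusted p = 2.47e-05). Antigen presentation had 6 of 20 higher (median 0.096, camera adjusted p = 0.0111), with B2M, a part of MHC class I, at 0.37. DNA replication and G1/S genes had 12 of 30 lower and 2 higher, 16 and 3 adjusted over the list alone (median -0.18, camera adjusted p = 0.00018; adjusted p = 0.0527 with an estimated correlation), such as PCNA (-0.33). ATF4 targets had 9 of 23 lower and 2 higher, 13 and 2 adjusted over the list alone (median -0.18, camera adjusted p = 4.31e-07; adjusted p = 0.0527 with an estimated correlation). Hypoxia and glycolysis genes (median -0.17, camera adjusted p = 0.00358) and the NADPH list (median -0.21, camera adjusted p = 0.00117) were lower. Neither the detoxification list (median -0.049, camera adjusted p = 0.752) nor the p53 list passed (median 0.027, camera adjusted p = 0.632); p53 targets had 6 of 31 higher and 5 lower.

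Radiation of E79Q cells raised RNA of chemokines, NF-kB targets and proteases, and of 2 of the 3 lists of NRF2 targets. CXCL8 went from 15.9 ± 0.180 to 60.6 ± 5.55 CPM (1.93, SE 0.078, adjusted p = 6.93e-16; n = 3 in each group). CXCL1 went from 35.1 ± 5.26 to 122 ± 6.35 (1.80, SE 0.096, adjusted p = 1.1e-13). IL6 went from 4.06 ± 0.381 to 11.6 ± 1.05 (1.51, SE 0.14, adjusted p = 9.85e-09). CDKN1A went from 38.2 ± 5.51 to 103 ± 5.98 (1.44, SE 0.084, adjusted p = 6.85e-13). AKR1C1 went from 58.1 ± 3.22 to 138 ± 8.67 (1.24, SE 0.082, adjusted p = 9.36e-12). The DNA clamp gene PCNA fell from 208 ± 2.11 to 149 ± 1.13 (-0.48, SE 0.051, adjusted p = 6.99e-08). Of 3557 genes 1944 rose and 1613 fell, 516 by over 2-fold. The largest rises held WNT7A (2.52, SE 0.22), CSF3 (2.35, SE 0.20), CXCL3 (2.21, SE 0.17) and ANGPTL4 (2.12, SE 0.31), and the largest falls SYT12 (-1.66, SE 0.078), RAB7B (-1.44, SE 0.11) and LFNG (-1.41, SE 0.085). The radiation effects in WT and E79Q cells shared 967 higher and 782 lower genes (183 and 137 expected), and 32 went opposite ways (317 expected).

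By list, irradiated E79Q cells had 14 of 21 chemokines and cytokines higher, 15 higher and 1 lower adjusted over the list alone (median 0.84, camera adjusted p = 1.33e-27), and 12 of 19 NF-kB targets, 14 adjusted over the list alone (median 0.54, camera adjusted p = 2.26e-20). The protease list had 16 of 23 higher and 2 lower, the same adjusted over the list alone (median 0.70, camera adjusted p = 6.01e-27). The mesenchymal list had 13 of 24 higher and 3 lower, the same adjusted over the list alone (median 0.36, camera adjusted p = 6.32e-11). Detoxification, iron and transport genes had 18 of 29 higher, 19 adjusted over the list alone (median 0.30, camera adjusted p = 2.15e-10), among them the autophagy receptor gene SQSTM1 (0.67). Glutathione and thioredoxin genes had 8 of 12 higher, 9 adjusted over the list alone (median 0.22, camera adjusted p = 0.000457). The NADPH list was lower (median -0.16, camera adjusted p = 0.0442; adjusted p = 0.182 with an estimated correlation, and 0.0864 without library 3 of irradiated E79Q cells). Interferon response genes had 10 of 26 higher, 11 adjusted over the list alone (median 0.46, camera adjusted p = 0.000457), such as IFIT2 (1.66). Antigen presentation genes had 9 of 20 higher, 11 adjusted over the list alone (median 0.24, camera adjusted p = 3.16e-05). Targets of p53 had 12 of 31 higher and 3 lower, 13 and 4 adjusted over the list alone (median 0.020, camera adjusted p = 0.00778). DNA replication and G1/S genes had 18 of 30 lower, 20 lower and 1 higher adjusted over the list alone (median -0.25, camera adjusted p = 1.2e-08). Cholesterol synthesis genes had 9 of 21 lower (median -0.16, camera adjusted p = 1.26e-05). Immediate early genes had 11 of 17 higher and 1 lower (median 0.36, camera adjusted p = 5.04e-06). Mitotic genes (median -0.076, camera adjusted p = 0.0123; adjusted p = 0.179 with an estimated correlation) were lower. Mitochondrially encoded genes (median 0.32, camera adjusted p = 0.000124; adjusted p = 0.246 with an estimated correlation) were higher, and the mitochondrial share was 1.93%, 2.58% and 2.64% in the untreated and 3.06%, 3.16% and 3.31% in the irradiated libraries.

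Radiation effects differed between genotypes for 201 genes, 130 higher and 71 lower in E79Q cells, and 26 by over 2-fold. GCLM had a radiation effect 0.66 higher on the log2 scale in E79Q than in WT cells (SE 0.073, adjusted p = 2.92e-06; n = 3 in each of 4 groups), CXCL8 0.80 (SE 0.12, adjusted p = 0.000234) and CDKN1A 0.72 (SE 0.12, adjusted p = 0.000678). SLC7A11 differed by 0.77 (SE 0.17, adjusted p = 0.013) and TXNRD1 by 0.33 (SE 0.064, adjusted p = 0.00485). In WT cells GCLM fell from 300 to 218 CPM and SLC7A11 from 293 to 182. The largest differences were those of F2RL2 (1.78, SE 0.20), NDRG1 (1.49, SE 0.12) and BBC3, a p53 target that promotes apoptosis (1.48, SE 0.25), and, on the lower side, DGAT2 (-1.249, SE 0.24) and DPF3 (-1.12, SE 0.17). MMP1 rose in both genotypes, but less in E79Q cells (-0.79, SE 0.075, adjusted p = 3.35e-07). Radiation effects were higher in E79Q cells for 6 of 12 glutathione and thioredoxin genes, as many adjusted over the list alone (median 0.34, camera adjusted p = 8.66e-14), and for 7 of 29 detoxification genes, 17 adjusted over the list alone (median 0.38, camera adjusted p = 7.2e-18). ATF4 targets had 6 of 23 higher, 16 adjusted over the list alone (median 0.29, camera adjusted p = 5.92e-18). Chemokines had 3 of 21 higher, 8 higher and 1 lower adjusted over the list alone (median 0.28, camera adjusted p = 4.34e-07). NF-kB targets had 3 of 19 higher, 4 adjusted over the list alone (median 0.20, camera adjusted p = 5.93e-07).

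Camera also placed the differences in radiation effect higher in E79Q cells for hypoxia (median 0.17, camera adjusted p = 9.25e-09), unfolded protein response (median 0.16, camera adjusted p = 5.93e-07), squamous (median 0.32, camera adjusted p = 9.58e-06), p53 target (median 0.0077, camera adjusted p = 0.0017) and mitochondrially encoded genes (median 0.50, camera adjusted p = 8.09e-16). It placed mitotic (median -0.13, camera adjusted p = 6.5e-07) and cholesterol synthesis genes (median -0.11, camera adjusted p = 0.000372) lower, with 1 and 0 of their members called. CHAC1, which degrades glutathione, differed by 1.06 and DDIT4 by 1.22, from lower untreated levels in E79Q cells. DDIT4 fell less in E79Q (22.9 to 13.5 CPM) than in WT cells. The count was 123 without library 2 of irradiated E79Q cells and 128 without library 2 or 3 of irradiated WT cells. It was higher with GC and length trends removed (542), without the 4 libraries with a GC trend (539), with DESeq2 (319) and with the groups compared alone (620).

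**Figure D4:**
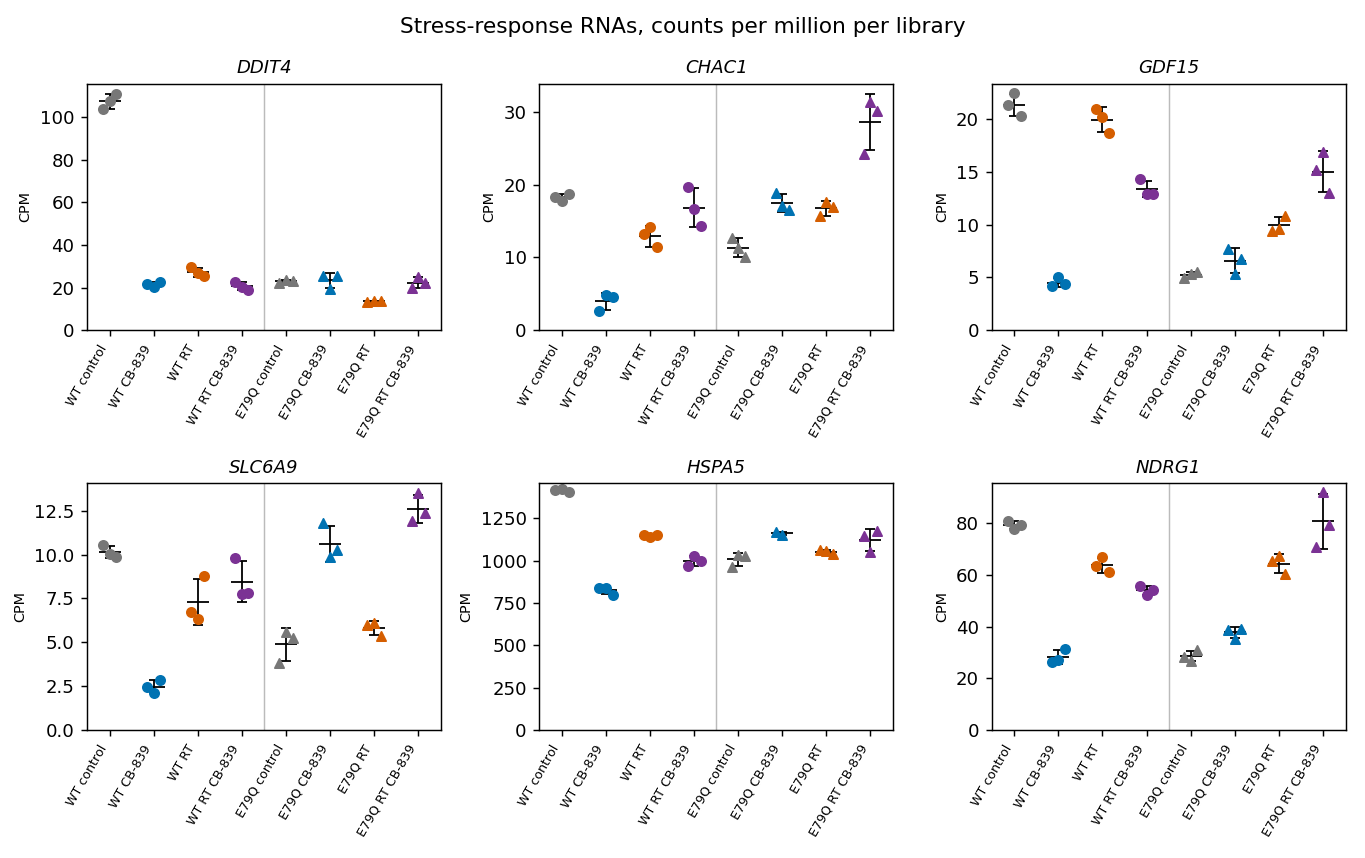
CPM of DDIT4, CHAC1, GDF15, SLC6A9, HSPA5 and NDRG1 in each of the 24 libraries (points), with the mean and SD of each group of 3. DDIT4 was at 107 ± 3.41 CPM in untreated WT cells and at most 27.25 CPM in any other group.

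In WT cells under CB-839, radiation raised chemokines, NF-kB targets, proteases and ATF4 targets. CDKN1A went from 27.7 ± 3.0 to 89.0 ± 4.54 CPM (1.68, SE 0.086, adjusted p = 5.84e-14; n = 3 in each group). CSF2 went from 2.19 ± 0.552 to 9.95 ± 0.656 (2.18, SE 0.20, adjusted p = 6.09e-09), CXCL8 by 1.68 and IL6 by 1.496 on the log2 scale. CHAC1 went from 3.97 ± 1.20 to 16.8 ± 2.68 (2.09, SE 0.16, adjusted p = 2.09e-10). STC2 went from 105 ± 4.84 to 220.4 ± 6.75 (1.07, SE 0.046, adjusted p = 1.7e-15). MKI67, a marker of cycling cells, went from 579 ± 31.0 to 396 ± 46.7 (-0.55, SE 0.094, adjusted p = 8.19e-05). Of 3774 genes 2111 rose and 1663 fell, with RRAD (2.14, SE 0.14) and ANGPTL4 (2.19, SE 0.31) among the largest rises and DIO2 (-1.61, SE 0.11) among the largest falls. Chemokines had 17 of 21 higher and 1 lower, the same adjusted over the list alone (median 0.91, camera adjusted p = 8.18e-24). NF-kB targets had 15 of 19 higher, 16 adjusted over the list alone (median 0.68, camera adjusted p = 4.74e-26). ATF4 targets had 19 of 23 higher, as many adjusted over the list alone (median 0.68 against -0.18 without the drug, camera adjusted p = 6.28e-29). The protease list had 17 of 23 higher (median 0.77, camera adjusted p = 3.36e-36). Antigen presentation had 16 of 20 higher (median 0.35, camera adjusted p = 8.45e-08). The detoxification list had 16 of 29 higher (median 0.39, camera adjusted p = 6.76e-11). The unfolded protein response had 12 of 18 higher (median 0.25, camera adjusted p = 1.73e-06). Mitotic genes had 13 of 30 lower (median -0.16, camera adjusted p = 3.41e-06). Homologous recombination and end joining genes had 11 of 29 lower and 1 higher (median -0.24, camera adjusted p = 2.94e-05, adjusted p = 0.19 with an estimated correlation), and 2 libraries here had a GC trend.

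In E79Q cells under CB-839, radiation again raised chemokines and NF-kB targets, and 2 of the 3 lists of NRF2 targets with them. The same 2 lists, glutathione and detoxification, passed in WT cells under the drug. CDKN1A went from 62.6 ± 2.33 to 145 ± 12.9 CPM (1.21, SE 0.081, adjusted p = 3.25e-11; n = 3 in each group). CSF2 went from 5.01 ± 1.07 to 16.5 ± 2.53 (1.72, SE 0.17, adjusted p = 4.02e-08). KRT14 went from 13.7 ± 0.513 to 36.7 ± 4.84 (1.42, SE 0.11, adjusted p = 4.7e-10). MKI67 went from 578 ± 36.9 to 380.2 ± 70.7 (-0.60, SE 0.094, adjusted p = 3.14e-05). Of 4667 genes 2445 rose and 2222 fell, and the count was 3108 without library 2 and 5697 without library 1 of irradiated E79Q cells with CB-839, and 1621 with the groups compared alone. Chemokines had 16 of 21 higher and 1 lower, 17 and 1 adjusted over the list alone (median 0.71, camera adjusted p = 4.51e-13). NF-kB targets had 16 of 19 higher (median 0.53, camera adjusted p = 2.31e-16). Detoxification genes had 23 of 29 higher, 24 adjusted over the list alone (median 0.40, camera adjusted p = 8.24e-16). Antigen presentation (median 0.32, camera adjusted p = 3.51e-07), p53 target (median 0.10, camera adjusted p = 0.000226), protease (median 0.54, camera adjusted p = 1.79e-21) and mesenchymal genes (median 0.17, camera adjusted p = 5.45e-05) were higher as lists. ATF4 targets had 10 of 23 higher (median 0.24, camera adjusted p = 1.64e-05; adjusted p = 0.093 with an estimated correlation). Homologous recombination and end joining genes had 19 of 29 lower (median -0.34, camera adjusted p = 1.12e-07; adjusted p = 0.0992 with an estimated correlation). The irradiated group here holds library 2, whose deviation followed GC content. The median of that list was -0.22 without it and -0.16 with trends removed.

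Under CB-839 the radiation effect differed between genotypes for 172 genes, 58 higher and 114 lower in E79Q cells. The ATF4 targets SLC6A9, a glycine transporter gene (-1.52, SE 0.21, adjusted p = 0.000104), CHAC1 (-1.37, SE 0.21, adjusted p = 0.000342), PSAT1 (-0.67, SE 0.068, adjusted p = 1.7e-06) and STC2 (-0.59, SE 0.064, adjusted p = 2.32e-06) had lower effects in E79Q cells (n = 3 in each of 4 groups). So did TNFAIP3 (-0.70, SE 0.099, adjusted p = 0.000132), CXCL1 (-0.79, SE 0.14, adjusted p = 0.00241) and the secreted neuropeptide precursor gene VGF (-1.505, SE 0.29, adjusted p = 0.00524), while KLK10 had a higher one (1.22, SE 0.13, adjusted p = 1.7e-06). ATF4 targets had 10 of 23 lower, 14 adjusted over the list alone (median -0.34, camera adjusted p = 2.05e-25). Chemokines had 4 of 21 lower, 8 adjusted over the list alone (median -0.30, camera adjusted p = 9.5e-07). NF-kB targets (median -0.21, camera adjusted p = 0.000474), the unfolded protein response (median -0.17, camera adjusted p = 3.32e-07) and mesenchymal genes (median -0.080, camera adjusted p = 1.66e-05) were also placed lower. Squamous (median 0.44, camera adjusted p = 1.9e-06) and hypoxia genes (median 0.16, camera adjusted p = 0.000214) were placed higher. The count was 92 and 105 without library 2 or 1 of E79Q cells with CB-839, 114 without library 2 of WT cells with CB-839, and 109 without library 2 or 3 of irradiated WT cells with CB-839. It was 340 with GC and length trends removed and 41 with the groups compared alone.

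Unirradiated WT cells given CB-839 had less RNA of amino acid and endoplasmic reticulum stress genes than untreated WT cells. DDIT4 went from 107 ± 3.41 to 21.6 ± 1.2 CPM (-2.32, SE 0.092, adjusted p = 9.98e-16; n = 3 in each group). GDF15 went from 21.4 ± 1.08 to 4.51 ± 0.456 (-2.24, SE 0.12, adjusted p = 1.93e-13). CHAC1 went from 18.2 ± 0.491 to 3.97 ± 1.20 (-2.20, SE 0.16, adjusted p = 6.93e-11). NDRG1 went from 79.4 ± 1.57 to 28.1 ± 2.76 (-1.496, SE 0.084, adjusted p = 3.81e-13). CDKN1A went from 55.9 ± 1.98 to 27.7 ± 3.0 (-1.01, SE 0.088, adjusted p = 2.29e-09). TPM1, an actin-binding tropomyosin, rose from 43.0 ± 2.50 to 109.9 ± 1.28 (1.35, SE 0.059, adjusted p = 5.74e-15). GPT2 fell from 78.1 ± 3.34 to 43.4 ± 1.90 (-0.85, SE 0.076, adjusted p = 4.65e-09). Of 2360 genes (3565 with GC and length trends removed) 1014 rose and 1346 fell, 257 by over 2-fold. ATF4 targets fell in 19 of 23 cases and rose in 1, in 21 and 1 adjusted over the list alone (median -0.91, camera adjusted p = 2.08e-59). The unfolded protein response had 9 of 18 lower, 14 adjusted over the list alone (median -0.24, camera adjusted p = 5.84e-12), such as HSPA5 (-0.78). Hypoxia and glycolysis genes had 14 of 23 lower and 1 higher, the same adjusted over the list alone (median -0.27, camera adjusted p = 7.42e-11).

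Chemokines and cytokines had 9 of 21 lower and 1 higher in WT cells given CB-839, 11 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 6.92e-07), IL6 with them (-1.10). NF-kB targets (median -0.22, camera adjusted p = 1.16e-08), p53 targets (median -0.076, camera adjusted p = 4.41e-05), glutathione and thioredoxin genes (median -0.22, camera adjusted p = 2.06e-05), the NADPH list (median -0.17, camera adjusted p = 0.000397) and interferon response genes (median -0.30, camera adjusted p = 0.00116) were lower as lists. So were antigen presentation (median -0.20, camera adjusted p = 0.00215) and squamous genes (median -0.35, camera adjusted p = 0.00133). Mitotic genes had 15 of 30 higher, 20 adjusted over the list alone (median 0.23, camera adjusted p = 1.09e-08), such as AURKA (0.33). For mesenchymal genes the median was -0.066, the mean was 0.12 and camera placed them higher (adjusted p = 9.49e-06), with 10 of 24 higher and 4 lower. The detoxification list had 11 of 29 lower and 1 higher (median -0.14, camera adjusted p = 0.000661; adjusted p = 0.122 with an estimated correlation). The glutamine list had 7 of 22 lower and 3 higher and did not pass (median -0.045, camera adjusted p = 0.0683), but passed without library 3 of untreated WT cells (adjusted p = 0.0436) or library 3 of WT cells with CB-839 (adjusted p = 0.0493).

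**Figure D5:**
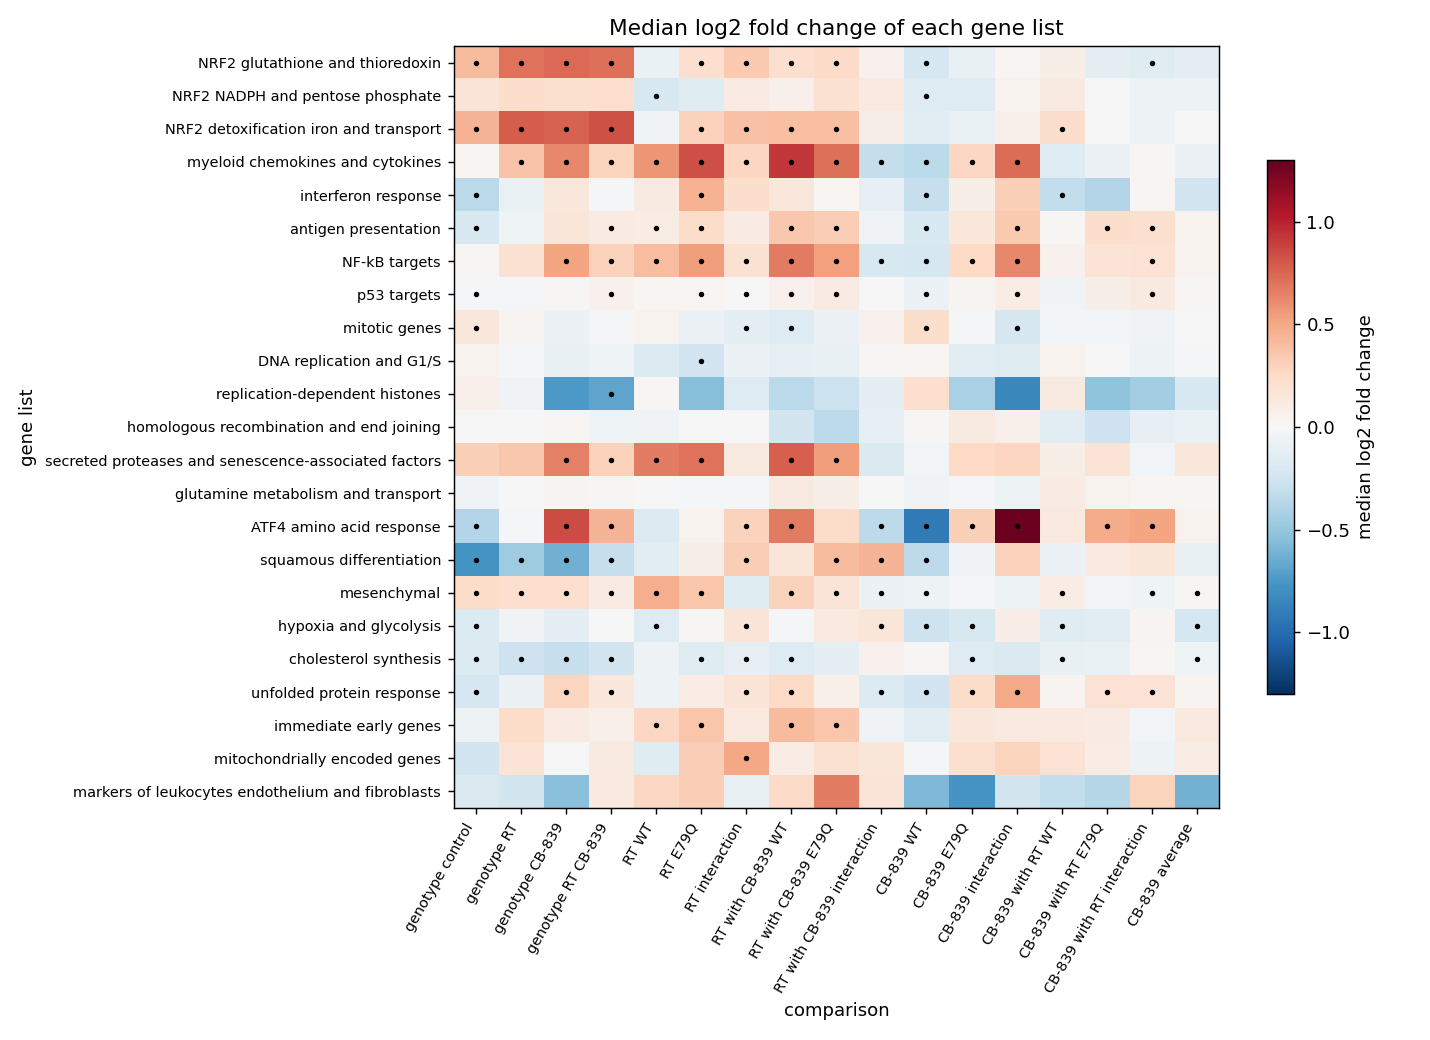
Median log2 fold change of the 23 gene lists (vertical axis) in the 17 comparisons (horizontal axis), as colour; a dot marks a camera test that passed at the preset and at an estimated correlation. The ATF4 list stood at -0.91 for CB-839 in unirradiated WT cells and at 0.31 in unirradiated E79Q cells.

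In unirradiated E79Q cells CB-839 raised ATF4 targets, the unfolded protein response and chemokines. PHGDH, which starts serine synthesis, rose from 224 ± 21.1 to 413 ± 7.07 CPM (0.88, SE 0.066, adjusted p = 1.64e-10; n = 3 in each group). TNFAIP3 went from 29.97 ± 3.05 to 61.2 ± 1.70 (1.03, SE 0.073, adjusted p = 4.51e-11). CDKN1A went from 38.2 ± 5.51 to 62.6 ± 2.33 (0.71, SE 0.085, adjusted p = 6.66e-07). TPM1 rose from 60.5 ± 2.87 to 177 ± 4.92 (1.55, SE 0.058, adjusted p = 1.08e-16). VIM fell from 176 ± 5.82 to 56.0 ± 3.97 (-1.65, SE 0.073, adjusted p = 2.12e-15). Of 3167 genes 1506 rose and 1661 fell, with ANGPTL4 (2.57, SE 0.30) and FAM129A (2.42, SE 0.17) among the largest rises and ELF3 (-2.06, SE 0.11) and DIO2 (-1.98, SE 0.11) among the largest falls. ATF4 targets had 13 of 23 higher and 1 lower, 15 and 1 adjusted over the list alone (median 0.31, camera adjusted p = 1.12e-10). The unfolded protein response had 13 of 18 higher, 16 adjusted over the list alone (median 0.23, camera adjusted p = 1.52e-06). Chemokines had 8 of 21 higher and 1 lower (median 0.27, camera adjusted p = 0.00138). NF-kB targets had 9 of 19 higher and 2 lower (median 0.26, camera adjusted p = 0.00138). Hypoxia and glycolysis genes had 11 of 23 lower and 2 higher (median -0.20, camera adjusted p = 0.00048), the glucose transporter gene SLC2A1 with them (-0.60). Cholesterol synthesis genes had 9 of 21 lower (median -0.16, camera adjusted p = 1.71e-05). The drug effects in WT and E79Q cells shared 281 higher and 340 lower genes (95.7 and 140.1 expected), and 323 genes went opposite ways (233 expected).

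The test of the difference in drug effect between unirradiated E79Q and WT cells called 2280 genes (3464 with GC and length trends removed), 1190 higher and 1090 lower in E79Q cells, 338 by over 2-fold. SLC6A9 was at 10.2 and 2.47 CPM in WT cells without and with the drug and at 4.89 and 10.6 in E79Q cells, a difference of 3.16 (SE 0.22, adjusted p = 8.07e-11) (n = 3 in each of 4 groups). CHAC1 differed by 2.82 (SE 0.21, adjusted p = 2.53e-10), GDF15 by 2.57 (SE 0.18, adjusted p = 9.8e-11) and CDKN1A by 1.72 (SE 0.12, adjusted p = 9.8e-11). SLC7A11 differed by 1.12 (SE 0.17, adjusted p = 2.86e-05) and CXCL8 by 0.99 (SE 0.13, adjusted p = 4.64e-06). On the lower side RGS4, a regulator of G protein signalling, differed by -2.62 (SE 0.29, adjusted p = 2.55e-07) and AKR1C1 by -0.64 (SE 0.14, adjusted p = 0.00311). ATF4 targets had 20 of 23 higher and 1 lower, the same adjusted over the list alone (median 1.27, camera adjusted p = 1.75e-74), among them PSAT1 (1.43) and STC2 (1.27). The unfolded protein response had 15 of 18 higher, 17 adjusted over the list alone (median 0.49, camera adjusted p = 4.67e-22). Chemokines had 12 of 21 higher, 14 adjusted over the list alone (median 0.73, camera adjusted p = 6.49e-11). NF-kB targets had 12 of 19 higher, 13 adjusted over the list alone (median 0.62, camera adjusted p = 2.47e-12). Antigen presentation (median 0.34, camera adjusted p = 1.13e-05) and p53 target genes (median 0.094, camera adjusted p = 0.00054) were placed higher and mitotic genes (median -0.22, camera adjusted p = 1.27e-08) lower.

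In irradiated WT cells CB-839 raised TPM1 from 62.0 ± 1.65 to 125 ± 4.45 CPM (1.01, SE 0.057, adjusted p = 3.94e-12; n = 3 in each group). NQO1 went from 292 ± 7.34 to 399.6 ± 14.3 (0.45, SE 0.066, adjusted p = 4.95e-05). It lowered the epithelial transcription factor gene ELF3 from 38.4 ± 1.18 to 14.1 ± 0.495 (-1.45, SE 0.090, adjusted p = 1.41e-11). ABCA1, a cholesterol exporter, went from 71.1 ± 3.45 to 30.2 ± 4.59 (-1.24, SE 0.099, adjusted p = 2.77e-09). VIM went from 50.1 ± 1.05 to 26.6 ± 2.72 (-0.91, SE 0.077, adjusted p = 8.09e-09). Of 1520 genes 797 rose and 723 fell. The detoxification list had 9 of 29 higher, 13 higher and 1 lower adjusted over the list alone (median 0.23, camera adjusted p = 7.09e-07). Interferon response genes had 7 of 26 lower (median -0.32, camera adjusted p = 4.44e-05). Hypoxia genes had 8 of 23 lower and 1 higher (median -0.16, camera adjusted p = 0.000293). Cholesterol synthesis genes had 6 of 21 lower (median -0.099, camera adjusted p = 0.000875). Mesenchymal genes had 8 of 24 higher and 4 lower (median 0.094, camera adjusted p = 4.44e-05). The glutamine list had 7 of 22 higher and 1 lower (median 0.10, camera adjusted p = 0.000376; adjusted p = 0.0535 with an estimated correlation). The ATF4 list was at median 0.13, camera adjusted p = 0.0117 (adjusted p = 0.432 with an estimated correlation), and at adjusted p = 0.132 without library 1 of irradiated WT cells with CB-839. The number of genes was 660 without that library, and 890, 967 and 714 without library 1, 2 and 3 of irradiated WT cells.

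In irradiated E79Q cells CB-839 raised ATF4 targets and the unfolded protein response. PHGDH went from 195 ± 3.33 to 410.4 ± 47.6 CPM (1.07, SE 0.066, adjusted p = 6.65e-12; n = 3 in each group). PYCR1, a proline synthesis enzyme, went from 32.6 ± 2.28 to 65.9 ± 6.78 (1.02, SE 0.076, adjusted p = 3.12e-10). KLK5 went from 50.6 ± 1.19 to 109 ± 13.7 (1.11, SE 0.075, adjusted p = 4.12e-11). ABCA1 went from 49.4 ± 2.46 to 13.4 ± 2.43 (-1.89, SE 0.11, adjusted p = 2.56e-12). VIM went from 145 ± 4.71 to 52.3 ± 3.19 (-1.47, SE 0.072, adjusted p = 1.01e-13). CXCL1 went from 122 ± 6.35 to 80.3 ± 2.94 (-0.60, SE 0.091, adjusted p = 2.13e-05). AKR1C1 went from 138 ± 8.67 to 93.6 ± 4.41 (-0.55, SE 0.080, adjusted p = 1.23e-05), while NQO1 went from 565 ± 8.63 to 755 ± 77.3 (0.42, SE 0.065, adjusted p = 3.04e-05). Of 4141 genes 2053 rose and 2088 fell. The count ran from 2872 to 5287 with 1 library left out and was 1566 with the groups compared alone. ATF4 targets had 17 of 23 higher, 18 adjusted over the list alone (median 0.48, camera adjusted p = 8.14e-23). The unfolded protein response had 10 of 18 higher (median 0.19, camera adjusted p = 2.52e-05). Antigen presentation had 9 of 20 higher and 2 lower (median 0.23, camera adjusted p = 0.00108). Homologous recombination and end joining genes had 12 of 29 lower and 2 higher (median -0.27, camera adjusted p = 0.00108; adjusted p = 0.381 with an estimated correlation). That list rested in part on library 2 with both treatments, whose deviation followed GC content. Its median was -0.12 without it (adjusted p = 0.0407) and -0.11 with trends removed (adjusted p = 0.0373). The drug effects in irradiated WT and E79Q cells shared 518 higher and 475 lower genes (103 and 94.6 expected), and 25 went opposite ways (197 expected).

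After radiation the drug effect differed between genotypes for 305 genes, 201 higher and 104 lower in E79Q cells. AKR1C1 (-1.37, SE 0.13, adjusted p = 3.58e-07), AKR1C2 (-1.33, SE 0.22, adjusted p = 0.000815), HKDC1 (-1.73, SE 0.32, adjusted p = 0.00289) and RGS4 (-1.83, SE 0.26, adjusted p = 0.000112) had lower drug effects in E79Q cells (n = 3 in each of 4 groups). Higher ones were those of DEPP1 (1.62, SE 0.25, adjusted p = 0.000323), DDIT4 (1.13, SE 0.14, adjusted p = 2.05e-05), PSAT1 (0.49, SE 0.068, adjusted p = 9.35e-05) and CDKN1A (0.53, SE 0.11, adjusted p = 0.00969). ATF4 targets had 11 of 23 higher, 14 higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 1.16e-23). Camera also placed the unfolded protein response (median 0.19, camera adjusted p = 2.96e-06), antigen presentation (median 0.20, camera adjusted p = 2.73e-05) and NF-kB targets (median 0.19, camera adjusted p = 0.00161) higher. It placed glutathione and thioredoxin genes (median -0.16, camera adjusted p = 0.00161) lower. The count was 152 and 172 without library 1 or 3 of irradiated E79Q cells, 172 and 165 without library 1 or 2 of irradiated WT cells, and 188 without library 2 or 3 of irradiated WT cells with CB-839. It was 569, 495 and 186 without library 1, 2 or 3 of irradiated E79Q cells with CB-839. It was 935 with GC and length trends removed, 726 without the 4 libraries, 472 with DESeq2 and 131 with the groups compared alone.

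Averaged over both genotypes, with and without radiation, CB-839 changed 4641 genes, 2264 higher and 2377 lower, 146 of them by over 2-fold. TPM1 rose by 1.20 (SE 0.029, adjusted p = 1.48e-21) on the log2 scale (n = 3 in each of 8 groups) and FN1 by 0.67 (SE 0.026, adjusted p = 6.13e-17). ABCA1 (-1.51, SE 0.055, adjusted p = 1.3e-17), ELF3 (-1.48, SE 0.049, adjusted p = 2.03e-18), VIM (-1.17, SE 0.037, adjusted p = 1.01e-18) and DIO2, which activates thyroid hormone (-1.43, SE 0.056, adjusted p = 5.6e-17), fell. The largest rises held PPP1R14C (1.43, SE 0.11), ANGPTL4 (1.36, SE 0.16) and TMEM255B (1.28, SE 0.11). Hypoxia and glycolysis genes had 16 of 23 lower and 3 higher, the same adjusted over the list alone (median -0.23, camera adjusted p = 4.47e-08), LDHA, the lactate dehydrogenase gene, with them (-0.38). Cholesterol synthesis genes had 9 of 21 lower (median -0.052, camera adjusted p = 9.82e-05), and mesenchymal genes had 9 of 24 higher and 5 lower (median 0.024, camera adjusted p = 5.84e-05). Interferon response genes had 10 of 26 lower and 1 higher (median -0.25, camera adjusted p = 0.0105; adjusted p = 0.129 with an estimated correlation). ATF4 targets did not pass on average (median 0.049, mean -0.0067, camera adjusted p = 0.268), nor did the glutamine list, with 9 of 22 higher and 3 lower (median 0.018, camera adjusted p = 0.0981). CDKN1A did not pass on average either (log2 fold change 0.04, adjusted p = 0.544).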

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

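The results below were picked out because the effect of radiation or of CB-839 differed between WT and E79Q cells by the test of the difference itself. Values are differences in log2 fold change, E79Q minus WT, and for lists the median of those differences. For the pattern in ATF4 targets, the removal of trends and the bounds of each test of an explanation were chosen only after the result was seen, while leaving out libraries and the comparison in irradiated cells were planned; for COL1A1 and COL1A2 they were chosen before the values they measure were seen.

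For the radiation effect without CB-839, 201 genes differed. Limma called 584 on the 12 libraries and at most 192 when residuals were reassigned. Of 100 reassignments, the real one included, 1 called as many, so chance arrangement of single libraries is unlikely to give the count. Here and below, a chance difference shared by a group's libraries is not excluded, since the labels do not state separate cultures. Single genes were F2RL2 at 1.78, NDRG1 at 1.49, BBC3 at 1.48, CXCL8 at 0.80, SLC7A11 at 0.77, CDKN1A at 0.72, GCLM at 0.66 and TXNRD1 at 0.33. Lower effects in E79Q cells were those of DGAT2 at -1.249, LYPD1 at -1.13 and DPF3 at -1.12. LYPD1 was not called without any 1 of 9 libraries, as in adjusted p = 0.159 without library 1 of irradiated E79Q cells. Lists were at 0.50 (mitochondrially encoded; 0.34 without library 1 of untreated E79Q cells, whose mitochondrial share was 1.93%), 0.38 (NRF2 detoxification), 0.34 (NRF2 glutathione), 0.32 (squamous), 0.29 (ATF4), 0.28 (chemokines), 0.20 (NF-kB), 0.17 (hypoxia), 0.16 (unfolded protein response) and 0.0077 (p53). Mitotic genes were at -0.13 and cholesterol synthesis at -0.11.

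For the radiation effect under CB-839, 172 genes differed. Limma called 37 on the 12 libraries and at most 1 when residuals were reassigned. Of 100 reassignments 1 called as many, so chance arrangement of single libraries is unlikely to give limma's count. Higher effects in E79Q cells were those of TAX1BP3 at 1.36, CRISPLD2 at 1.26 and KLK10 at 1.22. Lower ones were SLC6A9 at -1.52, VGF at -1.50, CHAC1 at -1.37, CXCL1 at -0.79, CXCL8 at -0.52 and CDKN1A at -0.47. TAX1BP3, CXCL8 and CDKN1A each lost the call when some single libraries were left out. Lists were at 0.44 (squamous), 0.16 (hypoxia), -0.080 (mesenchymal), -0.17 (unfolded protein response), -0.21 (NF-kB), -0.30 (chemokines) and -0.34 (ATF4).

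For the CB-839 effect without radiation, 2280 genes differed (3464 with trends removed). Limma called 2950 on the 12 libraries and at most 2 when residuals were reassigned. Of 100 reassignments 1 called as many, so chance arrangement of single libraries is unlikely to give limma's count. Single genes were SLC6A9 at 3.16, CHAC1 at 2.82, GDF15 at 2.57, CDKN1A at 1.72, IL6 at 1.248, SLC7A11 at 1.12, CXCL8 at 0.99 and CXCL1 at 0.65. Lower effects in E79Q cells were those of RGS4 at -2.62, CYP2B6 at -1.78, COL1A1 at -1.58 and KEAP1 at -0.30. COL1A1 was not called without library 2 of untreated E79Q cells (adjusted p = 0.126), nor KEAP1 without library 3 of WT cells with CB-839 (adjusted p = 0.116). Lists were at 1.27 (ATF4), 0.73 (chemokines), 0.62 (NF-kB), 0.49 (unfolded protein response), 0.34 (antigen presentation), 0.094 (p53) and -0.22 (mitotic).

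For the CB-839 effect after radiation, 305 genes differed. Limma called 118 on the 12 libraries and at most 1 when residuals were reassigned. Of 100 reassignments 1 called as many, so chance arrangement of single libraries is unlikely to give limma's count. Higher effects in E79Q cells were those of TMEM125 at 1.69, DEPP1 at 1.62, SAA1 at 1.29 and CDKN1A at 0.53. Lower ones were RGS4 at -1.83, HKDC1 at -1.73, AKR1C1 at -1.37, TXNRD1 at -0.33 and GCLM at -0.27. Without library 1 of irradiated E79Q cells TMEM125 (adjusted p = 0.0834) and SAA1 (adjusted p = 0.111) were not called. Lists were at 0.51 (ATF4), 0.20 (antigen presentation), 0.19 (NF-kB), 0.19 (unfolded protein response), 0.11 (p53), -0.060 (mesenchymal) and -0.16 (NRF2 glutathione). Without library 1 of irradiated E79Q cells with CB-839 the p53 and mesenchymal lists did not pass (adjusted p = 0.096 and 0.0544).

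Without radiation, ATF4 targets fell with CB-839 in WT cells and rose in E79Q cells. The median difference was 1.31 with GC and length trends removed and at least 1.24 with any 1 library left out. This argues against those trends and a single library as the whole cause. The difference was 0.51 in irradiated cells, which fits a drug response that differs by genotype. CHAC1 and SLC6A9 were lowest of the 8 groups in WT cells with CB-839, which also enter the ATF4 medians of 0.85, 0.68 and -0.34. DDIT4 was highest in untreated WT cells, which enter its falls by genotype, radiation and drug. A culture state of such a group cannot be told apart from these effects. Irradiated WT cells lacked the ATF4 fall (median 0.13). A genotype difference in drug response stays a hypothesis.

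COL1A1 and COL1A2 were high in library 2 of untreated E79Q cells (29.6 and 15.3 CPM, against at most 7.34 and 0.889 in the 23 other libraries). With trends on GC content and gene length removed, both stayed at least 2.07 above the other libraries of the group on the log2 scale, which argues against the trend of that library. Of 12 listed fibroblast transcripts, 3 (COL3A1, POSTN and FBN1) had at least 10 counts and were over 2-fold above both other libraries. The limit of 10 counts was not in the written rule, and without it DCN makes 4. Neither number meets or excludes the prediction of fibroblast RNA in that library. LUM had 0 counts and DCN 1 there, while SPARC (608 CPM) was too high in these cells to inform. No other explanation was tested.

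For the 12 comparisons of 3 libraries with 3, there are 10 splits of the 6 libraries, too few for a share under 0.05, and 1 of the 10 called as many genes in each. In fits of the 6 libraries alone the real split called 3881, 3025, 2745 and 225 genes for genotype (untreated, irradiated, CB-839, both). Radiation in WT and E79Q cells gave 4354 and 4829, and 3598 and 1621 under CB-839. CB-839 gave 2962 and 4000, and 2083 and 1566 after radiation. The highest of the other splits called 0 in each. For the average drug effect limma called 3346 genes and at most 132 with drug labels reassigned within the 4 pairs. Of 100 reassignments 1 called as many, so chance arrangement of single libraries is unlikely.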

How the results depend on the processing

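Removal of GC and length trends and the fit without the 4 libraries with a GC trend were tests chosen after the data were seen; the others were planned. Comparisons are given in the order E79Q against WT (untreated, irradiated, CB-839, both), radiation (WT, E79Q, difference; then under CB-839), CB-839 (WT, E79Q, difference; then after radiation) and its average. Limma-voom, DESeq2 size factors, upper quartile factors, no filter and the stricter filter each left 17 of 17 counts of genes within 1.5 times, and DESeq2 15. With the replicate block the 17 counts and 8 overlaps also stayed within 1.5 times. Among named genes DESeq2 kept the call and direction of 1361, with 6 newly called and 15 lost, limma-voom of 1364 (2 and 16) and upper quartile factors of 1349 (3 and 30). With trends removed 1287 were kept, 45 newly called and 47 lost. Leaving out 1 library at a time kept 10950 single calls, lost 720 and added 30. Scaling moved the median of all genes by at most -0.038.

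Tested against a 1.5-fold change the counts were 293, 159, 196 and 66, then 212, 238, 5, 161, 71 and 1, then 128, 119, 123, 13, 79 and 4, and 88, since a larger change is asked. DESeq2 gave 319 for the difference in radiation effect and 472 for that in drug effect after radiation. The groups compared alone gave more genes for genotype in irradiated cells (3025), radiation in WT cells (4354) and its difference (620). The counts with irradiated E79Q cells given CB-839 fell (225, 1621, 41, 1566 and 131). Deviations of libraries 1 and 2 of that group had SDs of 0.16 and 0.22, against at most 0.12 elsewhere. Its p-values rest on a spread pooled over all groups. The causes were not tested.

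With GC and length trends removed the counts were 2400 and 2093 (genotype, irradiated and both) and 542 and 340 (difference in radiation effect, without and with CB-839). They were 3565 and 3464 (CB-839 in WT cells, difference) and 935 (difference after radiation). Without the 4 libraries they were 2595 (genotype, irradiated), 4287 (radiation, WT), 539 (its difference) and 726 (difference in drug effect after radiation). The cause was not tested. At an adjusted p under 0.01 the shared calls were 700 (genotype, untreated and irradiated), 1090 (radiation in both genotypes), 850 and 864 (radiation without and with CB-839 in WT and E79Q), 342 (CB-839 in both genotypes), 391 (after radiation), 278 and 682 (CB-839 without and with radiation in WT and E79Q), fewer because the threshold is stricter.

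Leaving out each library gave, for genotype, 2400 to 2621, 1094 to 1191, 1733 to 2097 and 755 to 1654. For radiation it gave 2104 to 2271, 2734 to 3090 and 123 to 158, and under CB-839 2600 to 3559, 3108 to 5697 and 92 to 255. For CB-839 it gave 1655 to 1992, 2203 to 2697 and 1809 to 2133, after radiation 660 to 1453, 2872 to 5287 and 152 to 569, and for the average 4285 to 5274. Counts went both ways in some comparisons, and the cause was not tested.

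For genotype under both treatments, the median of homologous recombination genes lay between -0.21 and 0.029 with 1 library left out, the latter without library 2 of irradiated E79Q cells with CB-839 (adjusted p = 0.623). With trends removed CCNG1 turned to 0.013 (adjusted p = 0.869) for radiation in E79Q cells under CB-839. GCLM turned to 0.014 (0.883) and SLC38A2 to 0.020 (0.69) for CB-839 in irradiated E79Q cells. The cause was not tested. How far depth or the number of libraries limited the calls was not tested; of genes changed by 1.5-fold in a trial, 40% were recovered for the difference in radiation effect.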

Other observations

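The tests in this part were chosen before the values they measure were seen.

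CB-839 lowered RNA of ABCA1, which exports cholesterol, in each of the 4 pairs of groups: from 48.8 to 23.7 CPM in WT and from 22.2 to 6.11 in E79Q cells without radiation, and from 71.1 to 30.2 and from 49.4 to 13.4 after it (means of 3 libraries). One hypothesis was lower RNA of targets of LXR, the sterol-sensing receptor. The 8 listed targets other than ABCA1 had a median of -0.40 over the average drug effect and 6 were lower, among them ABCG1 (-1.31), SCD (-1.11) and SREBF1 (-0.93). Camera placed them lower than other genes (p = 5.14e-25; p = 6.02e-08 with an estimated correlation), in line with that hypothesis. LXR activity itself was not analysed here.

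TPM1 rose with CB-839 in unirradiated WT and E79Q cells. The hypothesis of higher YAP and TEAD target RNAs was left open: the median of 22 listed targets was 0.061 over the average drug effect, 8 were higher and 5 lower (camera p = 0.0513; p = 0.124 with an estimated correlation). The 2 unirradiated pairs differed in sign, with a median of -0.095 in WT (6 higher, 7 lower; p = 0.904) and 0.084 in E79Q cells (7 higher, 3 lower; p = 0.0132, and 0.0592 with an estimated correlation). That of higher SRF and MRTF target RNAs was left open too, with a median of 0.038 over 15 targets, 4 of them higher and 1 lower. Camera did not place them higher (p of 0.166). In unirradiated E79Q cells they ran against the hypothesis (median -0.20, 2 higher, 6 lower; p = 0.0142, and 0.255 with an estimated correlation), and in unirradiated WT cells the median was 0.055 (3 higher, 0 lower; p = 0.0958). In irradiated WT cells they were higher (median 0.175, 8 higher, 0 lower; p = 1.2e-06, and 0.0334 with an estimated correlation), and in irradiated E79Q cells the median was 0.038 (1 higher, 2 lower; p = 0.435).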
